A study of Mus musculus with 2 samples.

How the data were processed

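The series holds 2 samples of Neuro2a mouse neuroblastoma cells, 1 transfected with a non-specific control siRNA and 1 with an siRNA against Tmem132a, each hybridised as biotin-labelled RNA to 1 Affymetrix Mouse Genome 430 2.0 array. Groups were taken from the sample titles. RNA was isolated with Trizol and labelled by standard Affymetrix protocols, per the labels. The deposited values are probe-set signal intensity on a linear scale, which the authors calculated with MAS5, per the series text and the submitters' processing notes, whose version is not given in the sources used here. Scaling by the authors is not described, but both columns had a 2% trimmed mean of 500.003, so the signals of the arrays were already on 1 scale. The authors chose genes by fold change and detection call, per the series text. The calls were not used here, and low signals were filtered by size in their place.

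All computation was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots with matplotlib 3.10.9. Both arrays were set to the same 2% trimmed mean, which left the values almost as they were. Of 45101 probe sets, 64 Affymetrix controls were left out, and 45037 were used. Probe sets were named from the platform annotation: 34945 had 1 gene symbol, 932 had several and 9160 were not listed. An Entrez identifier found in the mouse gene table of assembly GRCm38.p6 was present for 34754 probe sets, and 0 symbols changed with it. Only probe sets with 1 symbol gave gene values. No coordinates are given, since the source of the annotation names no genome build.

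A probe set passed the filter when its mean signal over both arrays was at or above the median of all probe sets (77.25), which left 22519. Signals below the 20th percentile of all signals (14.5) were set to that floor, and 10 of the 485 genes that differed 2-fold had a probe set at the floor on 1 array, so that their ratio is a lower bound. The value of a gene is the mean log2 ratio, Tmem132a siRNA over control siRNA, over its probe sets past the filter, and 10678 genes had one. With 1 array per group no test was made, and a gene was counted as higher or lower when it differed at least 2-fold. Where several probe sets measured 1 gene, their SD around the gene mean and the agreement of the brightest with the next brightest were computed. The latter is a share of genes with an exact (Clopper-Pearson) 95% confidence interval, which treats genes as independent.

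A total of 46 gene lists were fixed, and 41 had at least 5 genes past the filter. The lists cover ER stress, the integrated stress response, metabolism, the cell cycle, neuronal genes, signalling pathways, protein and RNA machinery, and common reference genes. The other 5 lists were the TMEM132 family and markers of fibroblasts, glia, immune cells, and epithelium and endothelium. The median log2 ratio of each list was set against 10000 random lists of the same size drawn from 20 bins of matched mean signal, and a list was called outside them below percentile 2.5 or above 97.5.

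Genes were named by a fixed rule: Tmem132a and its family, Hspa5, Actb and Gapdh; the 12 highest and 12 lowest genes with at least 2 probe sets that all differed at least 1.5-fold the same way; the 5 highest and 5 lowest with 1 probe set whose mean signal was at or above the 75th percentile; and of each list up to 4 members past 2-fold, or the 2 with the largest ratio where fewer than 2 reached it. Gapdh has no gene value, since it was read from control probe sets alone, and further list members are given in the text as examples of their group. Tmem132b was not analysed here.

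The groups, the size rule, the lists, the naming rule and the alternatives were chosen before the data were examined. The alternatives were no rescaling, a median ratio of 0, quantile normalization, a loess of ratio on signal with a span of 0.3, no filter, a filter at the 75th percentile (462.8), no floor, a pseudocount of 79.2 in place of the floor, the brightest probe set of each gene, leaving out probe sets with x, s or a in their suffix, and, for lists, random lists without matching. The procedure was tested on simulated data for this comparison, with noise drawn from the disagreement of probe sets. It passed 46.9% of 49 genes changed 2-fold, 96% of 50 genes changed 3-fold, and 100% of 50 genes changed 4-fold and of 50 changed 8-fold, together with 151 of 10509 unchanged genes (1.44%). Of 200 random lists of 18 unchanged genes, 4% lay outside the range, as did 100% of 100 lists shifted by 0.4. The simulation does not include variation between cultures or error shared by the probe sets of a gene.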

Results

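Total RNA of Neuro2a cells, a mouse neuroblastoma line, was measured on Affymetrix Mouse Genome 430 2.0 arrays after transfection with a non-specific control siRNA or with an siRNA against Tmem132a, a gene of the TMEM132 family of single-pass membrane proteins. There was 1 array per group, so no value below has a replicate error and no test between the groups was possible. Differences are therefore described by size, as the log2 ratio of the Tmem132a siRNA array over the control siRNA array, and the number of arrays limits their precision. The table held 45101 probe sets per array. The median signal was 76.5 on the control siRNA array and 81.9 on the Tmem132a siRNA array, and both arrays had a trimmed mean signal of 500.003. After the signal filter, 22519 probe sets were left, 19316 of them with 1 gene symbol, and these gave values for 10678 genes.

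The comparison asks which transcripts differed in Neuro2a cells when Tmem132a was targeted. Tmem132a itself was lower on the array labelled with its siRNA. Its only assigned probe set, 1416845_at, had a signal of 1825.5 with the control siRNA and 435.6 with the Tmem132a siRNA, which is 23.9% of the control level, a log2 ratio of -2.07 and a 4.19-fold lower signal. Among 6867 probe sets with a mean signal between 500 and 2000, 5 had a ratio as low or lower, Tmem132a included. The free-text description of the Tmem132a siRNA sample repeats the wording of the control sample, while its title and treatment name the Tmem132a siRNA, and the lower Tmem132a signal goes with the title. Probe sets for Tmem132c, Tmem132d and Tmem132e did not pass the signal filter on these arrays. Their signals were at most 49.7 on the control siRNA array and at most 87.2 on the Tmem132a siRNA array, too dim to compare.

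Most genes differed little between the arrays. Of 10678 genes, 8763 (82.1%) lay within 1.5-fold, 224 (2.10%) were at least 2-fold higher on the Tmem132a siRNA array and 261 (2.44%) at least 2-fold lower, and 18 were at least 4-fold higher and 20 at least 4-fold lower. The spread of the ratios narrowed with signal: their SD was 0.78 over genes with a brightest probe set between 77.25 and 150 and 0.34 over genes above 2000. Of the 224 higher genes 106 lay in the dimmest of these ranges, as did 100 of the 261 lower genes. In simulated arrays with noise drawn from the disagreement of probe sets of 1 gene, 151 of 10509 unchanged genes passed the 2-fold rule. On the real arrays 485 genes did. That noise leaves out error shared by the probe sets of a gene and variation between cultures. The difference between these counts therefore does not measure how many genes truly changed.

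The genes named next had either several probe sets that all differed the same way or 1 bright probe set. Among those lower with the Tmem132a siRNA were genes of contractile and actin-associated proteins. Myl9, a regulatory light chain of myosin, had a signal of 3346 with the control siRNA and 478.9 with the Tmem132a siRNA (log2 ratio -2.80). Tnnt2, cardiac troponin T, had a log2 ratio of -1.70 over 2 probe sets, and Fblim1, which encodes a filamin-binding adaptor, one of -1.87. Acta2, smooth muscle actin, had a log2 ratio of -1.96, from 10520.2 to 2712.7. That value rests on 1416454_s_at, a kind of probe set that can share sequence with related genes such as other actins. With no signal filter, where its other probe sets entered with control signals of 5.9 and 26.7, the ratio of Acta2 was -0.39, and without probe sets of that kind it had no value.

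Further lower genes were of several kinds. Adamts4, an aggrecan-cleaving protease, had a log2 ratio of -2.26, and Cavin2, a component of the caveolar coat, one of -2.23 over 3 probe sets. Ltbp3, a binding protein of latent TGF-beta, had a ratio of -1.57, Npc2, a lysosomal cholesterol-binding protein, one of -1.65 and Mrvi1 one of -1.91. Nr2f1, a nuclear receptor, had a ratio of -1.66, the non-coding RNA Zfas1 one of -1.55, Nrep one of -1.47 and Selenbp1 one of -1.38. Dpy19l1, Zfp467 and Mier1 lay at -1.41, -1.33 and -1.33, and the 2 probe sets of Mier1 disagreed in size, with -0.65 and -2.01. With no signal filter Npc2, Ltbp3 and Mier1 no longer passed the 2-fold rule, with ratios of -0.43, -0.79 and -0.12. Zfp467 no longer did with a pseudocount of 79.2 added to the signals (-0.88), nor Dpy19l1 when measured by its brightest probe set (-0.998).

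Among the genes higher with the Tmem132a siRNA were several of stress responses. Srxn1, which encodes sulfiredoxin, had a log2 ratio of 1.67 over 3 probe sets that ranged from 1.54 to 1.78. Atf6, the endoplasmic reticulum (ER) stress sensor, had a ratio of 1.34 over 3 probe sets, and its brightest probe set went from 324.2 to 972. Atf3 and Trib3, targets of the stress-induced factors ATF4 and CHOP, had ratios of 1.39 and 1.23. The largest ratio in this group was that of Akap3, an A-kinase anchoring protein, at 2.02. Galnt3, an enzyme of mucin-type O-glycosylation, had a ratio of 1.42, Cyb5r1 one of 1.34, Stmn4, a stathmin, one of 1.33 and Fhdc1 one of 1.51.

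Other higher genes passed the 2-fold rule in some settings and not in others. Orai2, a store-operated calcium channel subunit, had a gene ratio of 1.69, but its probe sets gave 0.68 and 2.69 and the dimmer one had a control signal of 21.1. Bend6 (1.55), Serpina1b (1.40), Prrt4 (1.28), Atcay (1.25), Gramd3 (1.22), Plekhh1 (1.22) and Wdr35 (1.19) lost the 2-fold size when the same pseudocount was added, as did Orai2 (0.77). Orai2, Atcay and Gramd3 also lost it when measured by their brightest probe sets (0.68, 0.69 and 0.78). Fhdc1 lost it with no signal filter, where its ratio was 0.38.

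**Figure D1:**
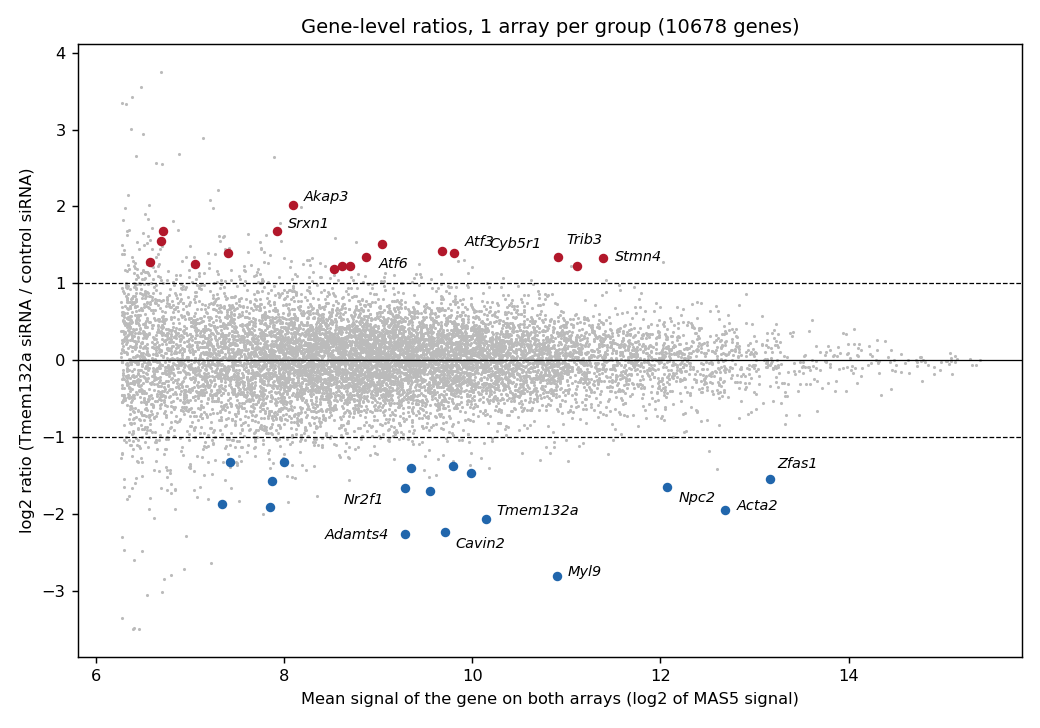
Log2 ratio of the Tmem132a siRNA array over the control siRNA array (vertical axis) against the mean log2 MAS5 signal of the gene on both arrays (horizontal axis), with 1 grey point for each of 10678 genes, and red and blue points for the higher and lower genes chosen by the fixed rule over all genes. The dashed lines mark 2-fold, and Tmem132a (-2.07) and Myl9 (-2.80) lie far below them at high signal, where the grey points are narrowly spread.

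**Figure D2:**
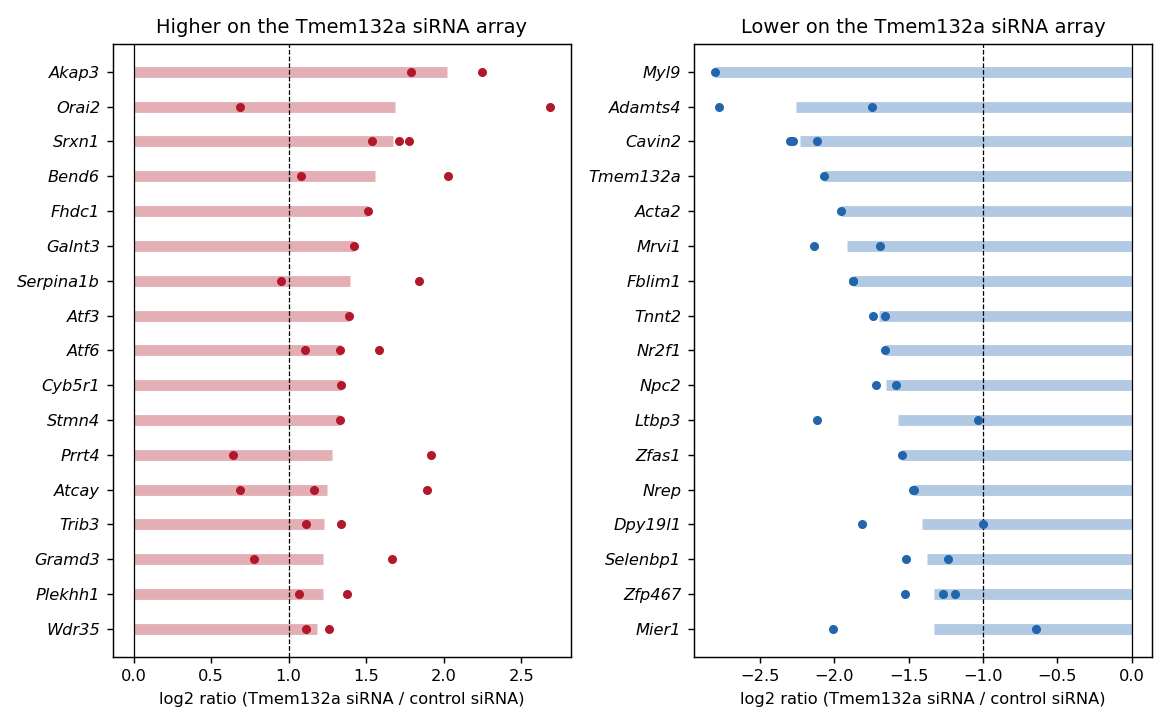
Log2 ratios of the named higher genes (left, red) and lower genes (right, blue), where bars give the gene value and each point is 1 probe set past the signal filter on the same 2 arrays. The 3 probe sets of Srxn1 and of Cavin2 lie close together, while those of Orai2 (0.68 and 2.69) and Mier1 (-0.65 and -2.01) lie far apart.

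Probe sets of the same gene gave an internal measure of technical error, within the same 2 RNA samples. Over 5072 genes with at least 2 probe sets past the filter, log2 ratios had an SD of 0.39 around their gene's mean. Of 157 genes that were 2-fold by their brightest probe set, 82 were at least 1.5-fold the same way by the next brightest (52.2%, exact 95% confidence interval 44.1% to 60.3%), and 127 (80.9%) were on the same side of 0. The share of all next-brightest probe sets at least 1.5-fold higher was 10.1%, and the share at least 1.5-fold lower was 10.7%. A total of 32 higher and 40 lower genes had a gene ratio of at least 2-fold and several probe sets that all differed at least 1.5-fold the same way.

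Gene groups fixed in advance were compared next, each by the median log2 ratio of its measured genes and by the percentile of that median among 10000 random lists of equal size and matched signal. Of 41 groups, 15 lay outside the central 95% of their random lists, 5 higher and 10 lower, where 2.05 would be expected by chance if genes were independent. Genes of one pathway vary together, so a percentile describes these 2 arrays and not what another pair of cultures would show.

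Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, were higher as a group on the Tmem132a siRNA array. Of 18 measured genes, 16 had a ratio above 0, 8 were at least 1.5-fold higher and 0 at least 1.5-fold lower. The median was 0.47, above all 10000 random lists (percentile 100). Beside Atf3 and Trib3, the group held Ddit3, which encodes CHOP, at 1.01, the cystine transporter Slc7a11 at 0.76, and Ppp1r15a, the regulatory subunit of an eIF2-alpha phosphatase, at 0.71. Atf4 itself had a ratio of 0.31 and Ero1a one of -0.48.

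Aminoacyl-tRNA synthetases and enzymes of serine synthesis showed the same direction. Of 17 genes, 15 had a ratio above 0, with a median of 0.49 (percentile 100). Wars and Eprs, the synthetases for tryptophan and for glutamate and proline, had ratios of 0.97 and 0.67, and Psat1 and Phgdh of serine synthesis 0.48 and 0.39. The mitochondrial serine hydroxymethyltransferase Shmt2 and the methionine synthetase Mars1 were below 0, at -0.67 and -0.04.

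ER chaperones and folding enzymes were not higher as a group. Their 20 genes had a median of -0.07 (percentile 17.2), with Hspa5, the main ER chaperone, at 0.29, Pdia4 at 0.43 and calnexin (Canx) at -0.85. The difference between the medians of the ATF4 and CHOP targets and the chaperones was 0.55, outside the range of -0.26 to 0.24 that held 95% of the pairs of random lists. Genes of unfolded protein response signalling and ER-associated degradation had a median of 0.22 (percentile 97.6), with Atf6 at 1.34, Wfs1 at 0.83 and Os9 at -0.53. That group lost its place outside the random lists in 7 of 11 alternative settings, among them the 75th percentile filter, where its median was 0.10.

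Immediate early genes were higher as a group, with a median of 0.31 over 19 genes (percentile 99.7). Egr1 had a ratio of 1.27, from 2449.7 to 5918.4, Dusp1 one of 0.56 and Jun one of 0.46, while Nr4a2 lay at -0.72, and Atf3 belongs to this group as well. Targets of NRF2, the regulator of the oxidative stress response, had a median of 0.23 over 18 genes (percentile 98.5), with Srxn1 at 1.67, the glutathione synthesis enzyme Gclc at 0.71 and Hmox1 at 0.56. The latter group was no longer outside the random lists without x, s and a probe sets, or with random lists not matched on signal.

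Genes of glycolysis and the hypoxia response were lower as a group on the Tmem132a siRNA array. Of 22 genes, 20 had a ratio below 0, with a median of -0.28 (percentile 0.03). Adm, which encodes adrenomedullin, had a ratio of -1.29 and the glucose transporter Slc2a1 one of -1.04, over 3 probe sets. Pdk1 and Bnip3 lay at -0.88 and -0.72, while Car9 and Egln3, also hypoxia-responsive, were the exceptions with 0.57 and 0.52. Genes of fatty acid synthesis had a median of -0.22 over 12 genes (percentile 2.43), with the transcription factor gene Srebf1 at -0.82 and Fads2 at -0.78. This group lost its place outside the random lists in 4 of 11 alternative settings.

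Genes of the TGF-beta and BMP pathways had a median of -0.37 over 18 genes (percentile 0.01), of which 14 were below 0. The receptor Tgfbr1 had a ratio of -1.06, Id3 one of -0.72 and Smad5 one of -0.71, while Smad3 lay at 0.57. With no signal filter the median was -0.17 and lay inside the random lists. WNT pathway genes had a median of -0.25 over 18 genes (percentile 1.56), with the receptor Fzd7 at -1.77, the ligand Wnt5a at -1.32 and the feedback gene Nkd1 at 1.13, and with no signal filter each of these 3 genes was under 2-fold. The WNT group was no longer outside the random lists with the 75th percentile filter. Genes of NF-kB and cytokine responses had a median of -0.39 over 10 genes (percentile 1.18), with Cxcl10 at -1.13 and Tnfaip3 at -0.93, and lost this place in 2 of 10 alternative settings.

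Genes of S phase and DNA replication had a median of -0.19 over 24 genes (percentile 0.50), with 18 below 0. Thymidine kinase 1 (Tk1) had a ratio of -1.21, from 2531.6 to 1091.7, and Mcm4 one of -0.72. Thymidylate synthase (Tyms) had a ratio of -1.23, but its probe sets gave -0.42 and -2.03. G1 cyclins and cell cycle inhibitors had a median of -0.21 over 16 genes (percentile 1.73), with E2f3 at -0.62, and genes of G2 and M phase one of -0.15 over 23 genes, which lay inside the random lists (percentile 3.49), with Kif20a at -0.81. The S phase group lost its place outside the random lists with the 75th percentile filter (median -0.14), and the G1 group did so with no filter (-0.18) and with unmatched random lists.

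Neuronal transcription factors had a median of -0.26 over 18 genes (percentile 0.44), with Hes6 at -1.03, Isl1 at -0.51, Mycn at -0.48 and Hand1 at 1.05, where Hand1 was dim (56 and 116.1). Id3 (-0.72), Id2 (-0.38) and Id1 (0.28) were counted both here and among the TGF-beta and BMP genes, and Mycn also in the G1 group. Genes of the neuronal cytoskeleton and differentiation had a median of -0.16 over 24 genes (percentile 2.01), with L1cam at -0.95 and Mapt, the tau gene, at -0.54, against 1.33 for Stmn4. The former group was inside the random lists in 2 of 11 alternative settings and the latter likewise in 2 of 11. A set of 11 common reference genes was also lower, with a median of -0.28 (percentile 0.77), and its members ran from -0.48 for Gusb to 0.59 for Tbp, with Actb at 0.01. That set was inside the random lists when each gene was measured by its brightest probe set (median -0.05) and without x, s and a probe sets (-0.15).

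**Figure D3:**
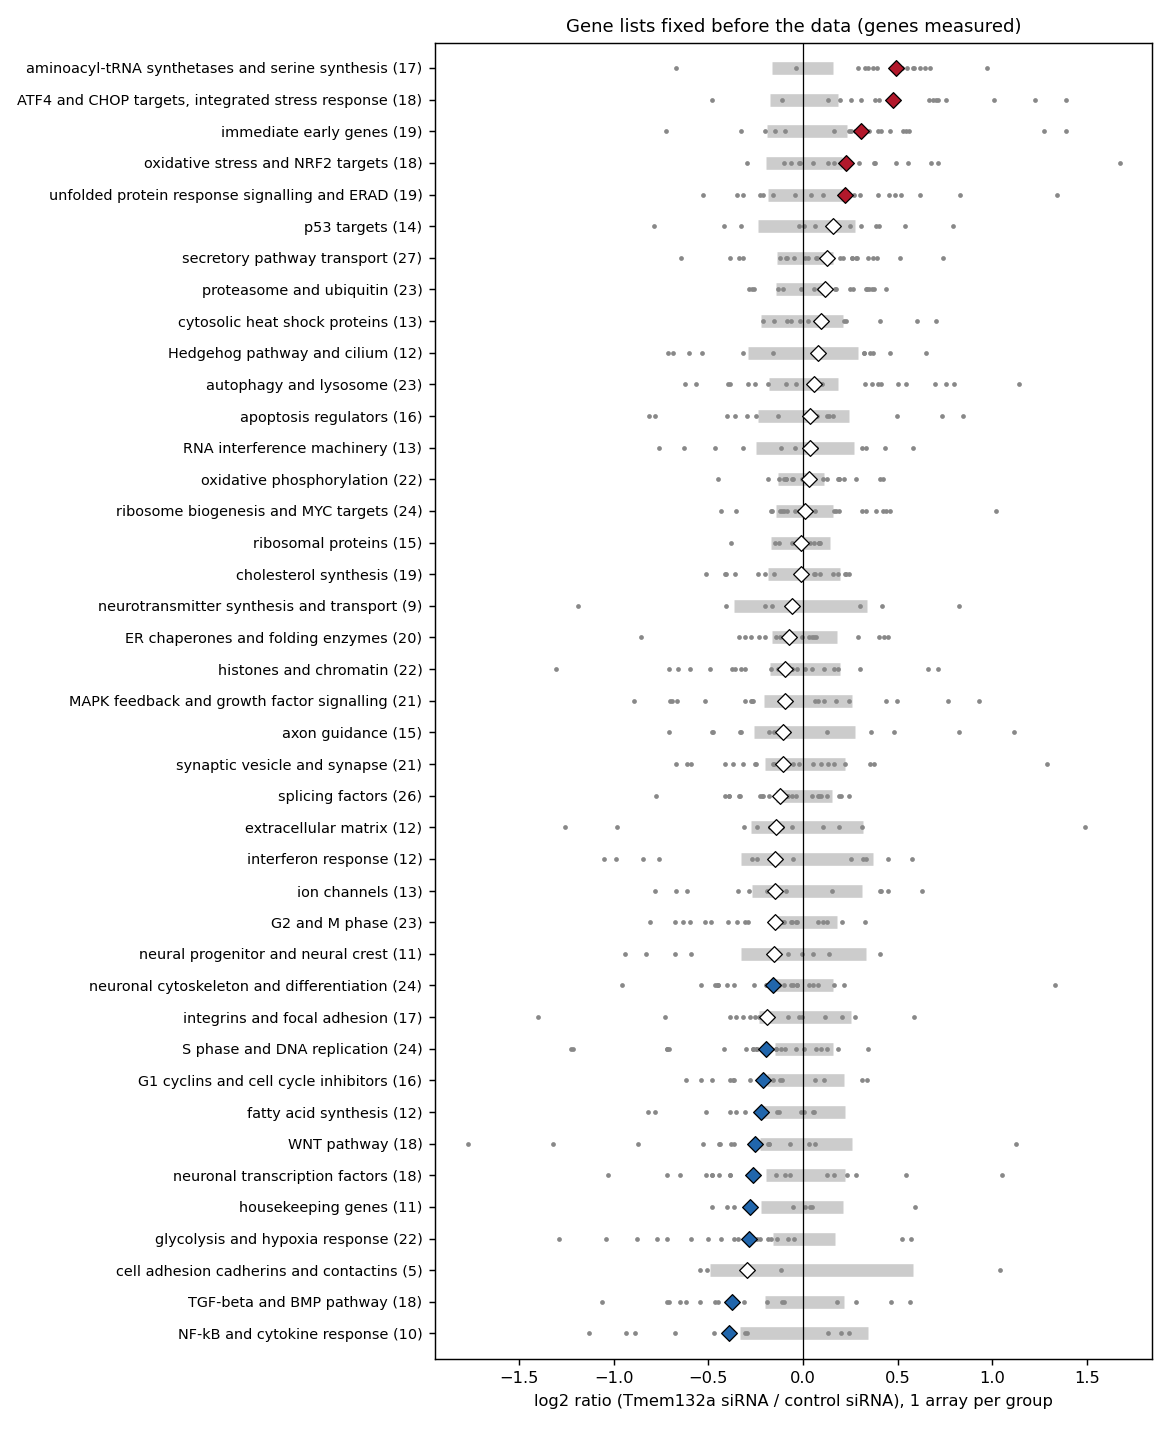
Log2 ratios of the Tmem132a siRNA array over the control siRNA array (horizontal axis) for the 41 gene groups, with the number of measured genes in brackets. Grey points are single genes, diamonds are group medians, and grey bars hold the central 95% of 10000 random list medians; red and blue diamonds lie above and below their bars, such as those of the ATF4 and CHOP targets (0.47) and the TGF-beta and BMP pathway (-0.37).

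The remaining groups lay inside their random lists. Among those of cell structure and signalling, integrins and focal adhesion had a median of -0.19 with Itga8 at -1.40, extracellular matrix one of -0.14 with Timp2 at -1.26, and cadherins and contactins one of -0.30 over 5 genes. Neural progenitor and neural crest genes had a median of -0.15, but by the brightest probe set of each gene it was -0.58 and lay outside the random lists. The median was -0.11 for both axon guidance and synaptic genes, -0.15 for ion channels, -0.06 for neurotransmitter genes, -0.10 for MAPK feedback genes and 0.08 for Hedgehog and cilium genes. Sv2c, a synaptic vesicle protein, had a ratio of 1.29 and acetylcholinesterase (Ache) one of -1.19. Interferon response genes, which siRNA can induce, had a median of -0.15 over 12 genes (percentile 15.6), with Ifitm3 at -1.05 and Rsad2 at 0.58, and genes of the RNA interference machinery one of 0.04.

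Among groups of general cell functions, the proteasome had a median of 0.12 (percentile 95.7) and secretory transport one of 0.13 (percentile 92.6), with Sec23b at 0.74. Medians were 0.16 for p53 targets, with Bbc3 at 0.79, and 0.04 for apoptosis regulators, 0.10 for cytosolic heat shock proteins, 0.06 for autophagy and lysosome, 0.03 for oxidative phosphorylation and 0.01 for ribosome biogenesis. They were -0.01 for ribosomal proteins and for cholesterol synthesis, -0.12 for splicing factors and -0.09 for histones and chromatin, where Dnmt3b had a ratio of -1.30 over probe sets that gave -2.14 and -0.47. In at least 1 alternative setting 8 of the 26 groups inside their random lists lay outside them: besides the neural progenitor genes, those of G2 and M phase, integrins, extracellular matrix, proteasome, secretory transport, splicing factors and chromatin. Of the group members given above at 2-fold or more, Ddit3, Slc2a1, Tgfbr1, Hes6, Hand1, Tyms, Cxcl10, Ifitm3, Ache, Timp2 and Dnmt3b were under 2-fold in at least 1 alternative.

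Markers of other cell types were mostly too dim to be measured. Of 14 fibroblast and mesenchyme genes with a probe set, 2 passed the filter, Acta2 and S100a4, the latter at 0.01. Of 14 genes each for glia, for macrophages and lymphocytes, and for epithelium and endothelium, 4, 2 and 1 passed, and these differed both ways. Of the glial genes, Pmp22 lay at 0.06 (3272.9 on the control siRNA array), Mbp at -0.18, Cnp at -0.42 and Erbb3 at 1.37 (128.9). Csf1r lay at -0.10, Laptm5 at 0.09 and Epcam at 1.04 (70.9), and both Erbb3 and Epcam were under 2-fold with no signal filter. Immune markers below the filter were mostly higher, such as Tyrobp (16.5 to 90.5), Cd14 (4.2 to 58.3) and Cd3e (13 to 44.2). A dim probe set of Laptm5 (35.1 to 9.4) was at least 2-fold lower. Dim probe sets of 1 list could thus differ mostly the same way on these arrays. The ratio of 3' to 5' signal, a measure of RNA integrity and labelling, was 1.52 for Actb and 0.953 for Gapdh on the control siRNA array, and 1.69 and 0.994 on the Tmem132a siRNA array. For Tfrc it was 4.41 on the control siRNA array and 3.75 on the Tmem132a siRNA array, and for Pcx 3.83 and 2.31, so the ratio was higher on the Tmem132a siRNA array for Actb and Gapdh and lower for Tfrc and Pcx. The 9 bacterial hybridisation controls had log2 ratios between -0.17 and 0.14.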

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

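No test in this part was chosen after its result was seen. Probe sets without a single gene symbol were not part of the gene comparisons, and 89 of the 3203 that passed the signal filter were at least 2-fold higher on the Tmem132a siRNA array than on the control siRNA array, while 87 were at least 2-fold lower. These shares, 2.78% and 2.72%, stood beside 2.49% and 2.88% of the 19316 named probe sets. Among the brighter ones, 1453686_x_at (343.7 with the control siRNA, 989.7 with the Tmem132a siRNA) and 1421683_at (549.5 and 1431.8) had log2 ratios of 1.53 and 1.38, and 1417177_at (2827.3 and 1124.9) and 1460208_at (840.5 and 344.9) had log2 ratios of -1.33 and -1.29.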

How the results depend on the processing

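All alternatives were planned. Tmem132a stayed at least 2-fold lower in each, and scaling moved the median log2 ratio of all genes by at most 0.0072. The filter and the pseudocount moved the counts of genes most. With no filter 1312 genes were at least 2-fold higher and 881 lower, so 59.8% of them were higher against 46.2%, and 28.0% of the genes 2-fold by the brightest probe set had a next brightest at least 1.5-fold the same way; 367 of the 485 genes were shared. With the 75th percentile filter the counts were 44 and 90 (32.8% higher), the agreement was 73.0% and 97 genes were shared, with fewer genes measured. The pseudocount, which shrinks ratios of dim genes by construction, left 49 and 79, all among the 485. No gene turned from 2-fold higher to 2-fold lower or the reverse in any alternative. Of 59 named genes past 2-fold, 24 stayed so in every setting that measured them, among them Tmem132a, Myl9, Cavin2, Adamts4, Tnnt2, Nr2f1, Srxn1, Atf6, Atf3, Trib3 and Egr1. With no filter Hand1 (-0.53) and Sema3f (-0.38) changed sign, as did Becn1 with the 75th percentile filter (-0.0731) and without x, s and a probe sets (-0.20); its 4 probe sets disagree, and dimmer probe sets enter for Hand1 and Sema3f. Between 10 and 18 gene groups lay outside their random lists. The ATF4 and CHOP targets, tRNA synthetases, immediate early genes and glycolysis and hypoxia genes did so in all 11 alternatives, the other 11 groups lost it in at least 1, and 8 of the other 26 gained it in at least 1. Low signal limits the dim genes, where the SD of ratios was 0.78.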

Other observations

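Of what follows, the control-array signals of fibroblast transcripts and the question of culture or off-target differences were tests chosen after the result was seen. The 4 contractile and actin-associated genes weighed here and 3 further gene groups were also chosen after the named genes and group medians were known. The 3 groups were chosen without genes whose values had been seen. Genes linked to ATF4 outside the fixed lists had a median log2 ratio of 0.34 over 20 genes, 16 of them above 0. Cth, an enzyme of cysteine synthesis, lay at 0.98, the glycine transporter Slc6a9 at 0.69, Gtpbp2 at 0.68 and the tRNA exporter Xpot at 0.64, against -0.84 for Cbs. Hypoxia-responsive genes outside the lists had a median of -0.39 over 18 genes, 13 of them below 0, with Hilpda at -0.93, Car12 at -0.90 and Egln1 at -0.67. Actin cytoskeleton genes outside the lists had a median of -0.36 over 20 genes, 16 of them below 0. Flna, which encodes the actin cross-linker filamin A, lay at -1.18 (8141 to 3601.4), Tgfb1i1 at -0.89, Smtn at -0.87 and Myh10 at -0.57, while Actn1 lay at 0.38 and Actg1 at -0.07.

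In the autophagy and lysosome group, whose median lay inside its random lists, single genes differed in size. Atg12, Gabarapl1 and Sqstm1 had log2 ratios of 0.80, 0.76 and 0.70, and Gabarapl2 and Ulk1 had ratios of -0.62 and -0.57, but the 2 probe sets of each disagreed, with -1.21 and -0.03 for Gabarapl2 and -1.08 and -0.05 for Ulk1. Tenascin C (Tnc) had a ratio of 1.49 at low signal (54.6 to 153.3), which was under 2-fold with no filter (0.74) and with the pseudocount (0.80). Fibronectin (Fn1) had a ratio of -0.98, and the transcription factor genes Zic1 and Snai2 lay at -0.83 and -0.67.

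The higher ATF4 and CHOP targets beside ER chaperones whose median lay inside its random lists may reflect an integrated stress response without a matching chaperone response, as a hypothesis. An intensity-dependent scaling difference between the arrays was argued against, since the group's median was at least 0.466 in every alternative, a loess of ratio on signal among them. Its percentile of 100 after the loess adds little, since the random lists were already matched on signal. Dim probe sets near the filter were argued against too, since the group stayed above all random lists (percentile 100) with the 75th percentile filter. The ATF4-linked genes outside the lists also lay at percentile 100, which is what a wider ATF4 programme that moved would show. With 1 array per group, a culture difference or off-target siRNA effect unrelated to Tmem132a cannot be told apart from an effect of lower Tmem132a.

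The lower glycolysis and hypoxia genes may reflect a weaker hypoxia programme in the cells of the Tmem132a siRNA array. Against this reading, Vegfa (-0.08) and Hk2 (-0.05) of that group hardly differed. The common reference genes had a similar median (-0.28), although they lay inside their random lists in some alternatives. An intensity-dependent scaling difference between the arrays was argued against by the group's median, which was -0.26 or lower in every alternative, the loess among them. Its percentile of 0.04 after loess adds little, since the random lists were already matched on signal. The hypoxia-responsive genes outside the lists lay at percentile 0.01, which is what a wider hypoxia programme that moved would show. With 1 array per group, a culture difference or off-target siRNA effect unrelated to Tmem132a cannot be told apart from an effect of lower Tmem132a.

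The 4 lower contractile and actin-associated genes, Myl9, Acta2, Tnnt2 and Fblim1, had a median log2 ratio of -1.91, of which 100.95% was left after loess. That adds little, since they were picked for ratios far from those of most genes, which the loess follows. A scaling difference of that size was argued against by all genes together, of which 82.1% lay within 1.5-fold. Acta2 rests on 1416454_s_at and had a ratio of -0.39 with no filter. The abundant fibroblast transcripts Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn had control-array signals of at most 52.1. These lay below the median of all probe sets on that array (76.5) and gave no sign of many fibroblasts. That outcome was largely known beforehand, since these genes had not passed the filter (77.25). A small share of fibroblasts cannot be excluded, since dim probe sets of Col1a1, Col1a2 and Postn were lower, although that of Dcn was higher. Fewer mesenchymal cells, with low levels of these transcripts or without them, cannot be told apart from a difference within the Neuro2a cells. The reason is that S100a4 (0.011) was the only other marker past the filter. Dim markers differed both ways, but more of their probe sets were lower than higher. Thy1 (73.6 to 9.5), Pdgfra (96 to 39.7 and 79.2 to 6.1) and Postn (44.1 to 10.9) were at least 2-fold lower. So were Tagln (39.1 to 6.1) and a probe set each of Col1a2 (42.1 to 7.1) and Col1a1 (29.4 to 3.9). Another probe set of Col1a2 (52.1 to 81.1) was higher by less than 2-fold. Only Dcn (22.5 to 62.2) was as much higher, and Lum (13 to 27.4) was under 2-fold once the floor was applied. Those control signals of Pdgfra lay above the array median of 76.5. The actin genes outside the lists lay at percentile 0.02, so a wider actin cytoskeleton programme may have moved. With 1 array per group, a culture difference or an off-target siRNA effect stays open here too.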
